A study of Mus musculus with 8 samples.

How the data were processed

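The series holds 8 Affymetrix arrays of mouse CD4+ Tconv cells from lymph nodes of the B6 background, sorted as CD4+ cells without CD19, CD8a, CD11b, CD11c, CD25 and NK1.1, stimulated with beads against CD3 and CD28 and transduced by retrovirus, per the labels. The authors made each intensity with Affymetrix Power Tools and RMA, per the submitters' processing notes, which give no versions. The deposited table gives linear normalized intensity for 24922 probe sets in 8 arrays, with no missing values and no zeros, and any filter and the genome build are not stated, so no coordinates are given. Groups were taken from the labels: EOS+LEF1 (n = 3), GATA1+SATB1 (n = 3) and empty vector (n = 2).

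Values were taken to log2 without a pseudocount. Of the probe sets, 21425 carried exactly 1 gene symbol in the table's annotation, 1399 several and 2098 none. Only the first kind entered the gene tests, and for the 921 genes with several probe sets the probe set with the highest mean over all arrays was kept, giving 19752 genes. Gene identifiers of 21347 probe sets matched the reference table of mouse genes, 78 did not, and 0 symbols were changed. The 3 group means were fitted with limma 3.58.1 (R 4.3.3) to all 8 arrays by lmFit and eBayes (5 residual degrees of freedom, prior degrees of freedom 6.62), and the 3 contrasts were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Errors beside intensities are SD over arrays and those beside log2 differences are limma's SE. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, with camera at an estimated correlation and fry beside it. The 29 lists were written from textbook knowledge and hold 559 genes, of which 504 were measured, 22 lay only on probe sets of several genes and 33 were not in the table. The genes of the 4 transduced factors were left out of the list tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

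The comparisons, the lists, the test, the alternatives and the rule for named genes were chosen before the data were examined. The rule takes, per contrast, the factor genes and Foxp3 with Irf4 and Ikzf2, the 12 genes with the largest and the 12 with the most negative log2 difference among called genes whose arrays do not overlap between groups (predicted, olfactory, vomeronasal, microRNA and small nucleolar genes left out), and up to 4 members of each list with the smallest p. Alternatives were quantile normalization, median centring, only genes at or above the median level, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, only the 2 groups compared, a pseudocount of 16, stricter thresholds (adjusted p under 0.01, at least 2-fold), the replicate number as a block, and leaving out each array in turn. Leaving out an empty-vector array leaves 1, which is assumed to vary like the other groups. Added after the data were seen were a fit of all probe sets, a contrast of the 6 factor arrays with the 2 vector arrays, 5 gene classes formed by symbol, the share of genes of smallest p with the same sign in both simulated contrasts, and the tests of explanations in the closing section. For the shared vector arrays, unchanged groups were simulated 100 times. The gene test was tested on simulated data in 20 runs per contrast with 200 of 19752 genes changed: for GATA1+SATB1 against empty vector it recovered 92% of changes of 0.5 and 99.9% of changes of 1 on the log2 scale, with 6.21% of calls false, and for EOS+LEF1 against GATA1+SATB1 97% and 99.8%, with 6.79% false. For GATA1+SATB1 against empty vector camera called a list shifted by 0.2 in 20 of 20 simulated runs and an unshifted list in 1. Each gene was drawn independently in all these runs, while the estimated correlation within the Treg-up list was 0.434. The runs therefore do not show how either test behaves for genes that vary together.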

Results

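RNA from activated CD4+ conventional T cells (Tconv) of mouse lymph nodes was measured on 8 Affymetrix expression arrays. The cells carried retroviral cDNAs for a pair of transcription factors or an empty retroviral vector, which the labels call pMIG. The labels name 3 arrays EOS+LEF1, 3 GATA1+SATB1 and 2 empty vector, the last numbered 8 and 9. EOS, encoded by Ikzf4, is an Ikaros-family zinc finger protein that acts with FOXP3, and LEF1 is a nuclear effector of Wnt signalling. GATA1 directs erythroid and megakaryocyte development, and SATB1 organizes chromatin in T cells. The series asks how these pairs act on the transcriptional signature of regulatory T cells (Treg cells). The median deposited intensity per array ran from 200.3 to 209. Across probe sets, log2 values correlated at r = 0.9954 to 0.9972 between arrays of a group and at 0.9919 to 0.998 between arrays of different groups, probe sets not being independent replicates. The number of arrays limits the precision. The labels do not say whether arrays of a group came from separate cultures or animals, so each p measures only the spread between these samples. The numbers 8 and 9 occur in neither factor group, and the labels do not say whether all arrays were prepared together. A difference in preparation could therefore not be separated from any contrast with empty vector.

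The genes of the 4 transduced factors were measured first, because they can check the labels. None of them was raised past the threshold in the arrays labelled with it. Ikzf4 read 649 ± 72.2 (SD, n = 3) in the arrays labelled EOS+LEF1 and 529 ± 2.14 (SD, n = 2) with empty vector, a log2 difference of 0.29 (SE 0.0951, adjusted p = 0.373 in limma). In the arrays labelled GATA1+SATB1 its difference was 0.33 (adjusted p = 0.0845). Lef1 read 4891 ± 206 in the arrays labelled EOS+LEF1 and 5143 ± 278 with empty vector (log2 −0.07, adjusted p = 0.725). In the arrays labelled GATA1+SATB1, Gata1 read 366 ± 12.7 against 333 ± 28.4 with empty vector (log2 0.14, adjusted p = 0.353). Satb1 read 5147 ± 391 there against 6438 ± 646 (log2 −0.32, adjusted p = 0.0947). The table does not say whether these probe sets lie in the transduced cDNA. The values neither bear out nor contradict the labels, and groups are called by their labels throughout.

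**Figure D1:**
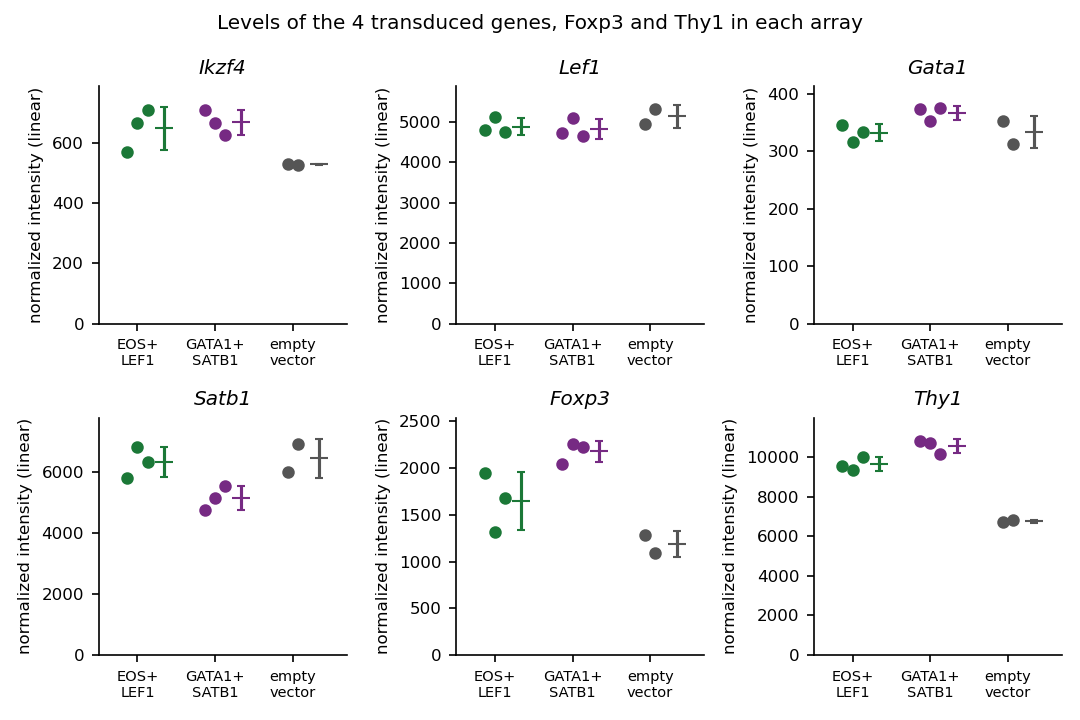
Normalized intensity on a linear axis in each of the 8 arrays (points), with the mean and SD of each group beside them, for the 4 transduced genes, Foxp3 and Thy1. Foxp3 averaged 2178 in the arrays labelled GATA1+SATB1 and 1189 with empty vector, while Gata1 averaged 366 and 333.

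The comparison of the arrays labelled GATA1+SATB1 with empty vector asks what this pair does to activated Tconv cells. Of 19752 genes, 439 differed (2.22%), 353 higher and 86 lower, and all 19 that differed at least 2-fold were higher. Igkv10-96, a variable segment of the immunoglobulin kappa light chain, rose most, to 236 ± 47.7 (SD, n = 3) from 60.6 ± 2.91 (SD, n = 2), which is 3.84-fold (adjusted p = 0.000554). Scd1, a desaturase that makes monounsaturated fatty acids, rose 2.97-fold (adjusted p = 0.0086). The metallothionein gene Mt2 rose 2.96-fold (adjusted p = 0.0401) and the histone gene H3c15 2.55-fold (adjusted p = 0.0138). Malat1, a long nuclear RNA, had the most negative difference, at 2821 ± 505 against 4786 ± 162 (log2 −0.78, adjusted p = 0.0279). The interferon-induced gene Ifit3 came next (log2 −0.76, adjusted p = 0.0195), and Slc28a2b (log2 −0.62) and Pik3ip1, an inhibitor of PI3 kinase signalling (log2 −0.54), fell as well. In limma, 3877 genes lay under an unadjusted p of 0.05, against 988 expected by chance. Quantile normalization called 349 higher and 153 lower. The count was 222 without EOS+LEF1 array 1, 20 without GATA1+SATB1 array 1, 5 without GATA1+SATB1 array 2, 273 without vector array 8 and 4 without vector array 9. It was 64 with array weights and 882 among genes above the median level. Igkv10-96 kept its call in each alternative that tested it. Its mean level lay below the median of 204 over all genes, so the fit of genes above the median level did not hold it. The other 7 genes lost their calls without GATA1+SATB1 array 2 (adjusted p 0.0683 to 0.152). All but Scd1 and H3c15 lost theirs without GATA1+SATB1 array 1 (0.0733 to 0.119), and all but Ifit3 without vector array 9. Calls also ended for Malat1 and Pik3ip1 without vector array 8 (0.0693 and 0.0644), for Mt2 and Pik3ip1 without EOS+LEF1 array 1 (0.0574 and 0.058), for Malat1, Mt2 and Pik3ip1 with array weights (0.0594, 0.0751 and 0.0801), and for Mt2 with a variance trend (0.127).

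Treg-up genes leaned upward, 9 of them past the test, and Treg-down genes did not lean one way. All 37 measured Treg-up genes lay above 0 in the arrays labelled GATA1+SATB1, with a median log2 difference of 0.44. Of them 9 rose and none fell (32 higher when adjusted over the list alone). Foxp3, the defining transcription factor of Treg cells, rose 1.84-fold, to 2178 ± 113 (SD, n = 3) from 1189 ± 139 (SD, n = 2; log2 0.88, SE 0.135, adjusted p = 0.0196). Tigit, an inhibitory receptor, rose 1.95-fold (adjusted p = 0.0292), and Lrrc32, whose product holds latent TGF-beta on the surface of Treg cells, 1.54-fold (adjusted p = 0.0237). The redox enzyme gene Glrx rose 1.62-fold (adjusted p = 0.031) and Penk, which encodes proenkephalin, 2.50-fold (adjusted p = 0.0489). Of 17 measured Treg-down genes, 3 rose and 1 fell (4 and 4 when adjusted over the list alone), with a median of 0.03. The 3 that rose encode cytokines. Il2, the growth factor that Treg cells consume and do not make, rose 1.80-fold (adjusted p = 0.0287), Il21 1.56-fold (adjusted p = 0.0292) and Ifng 1.54-fold (adjusted p = 0.0422). The gene that fell, Actn1, encodes an actin cross-linker (log2 −0.41, adjusted p = 0.0302). B cell markers and MHC class II genes leaned upward in the same arrays (medians 0.53 and 0.73). In limma's camera test with its preset correlation the Treg-up list passed (adjusted p = 4.84e-22). It did not pass with an estimated correlation (adjusted p = 0.256) or in fry (adjusted p = 0.0536). The Treg-down list did not pass (camera adjusted p = 0.451), and its median turned to −0.01 after quantile normalization and to −0.02 without GATA1+SATB1 array 2. Each of the 9 gene calls named here ended without GATA1+SATB1 array 1 (adjusted p 0.0604 to 0.116), GATA1+SATB1 array 2 (0.0877 to 0.141) or vector array 9 (0.189 to 0.265), where the Treg-up median was 0.29, and 7, all but Foxp3 and Lrrc32, with array weights (0.0555 to 0.088). Calls also ended for Lrrc32, Penk and Ifng without vector array 8 (0.0665, 0.0966 and 0.0752), for Penk and Ifng without EOS+LEF1 array 1 (0.0661 and 0.0591), and for Penk with median centring (0.0564) or a variance trend (0.12).

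Some genes of T cell activation and of effector programmes rose in the same arrays, and most members of these lists did not pass the test. Of the 37 Treg-up genes 13, and of the 24 activation genes 13, stand in another list too, so these lists are not independent. Of 24 activation genes 6 rose (15 higher and 1 lower when adjusted over the list alone, median 0.28). They included Nr4a2 and Egr2, early genes of T cell receptor signalling (log2 0.60 and 0.46, both with adjusted p = 0.0202). Havcr2, which encodes the inhibitory receptor TIM-3, rose by 0.94 and Tnfrsf9, which encodes the costimulatory receptor 4-1BB, by 0.74. Of 16 Th2 genes 5 rose (8 when adjusted over the list alone, median 0.44). Among these were Ccr8, a chemokine receptor gene also active in Treg cells (log2 1.04, adjusted p = 0.0344), Maf, a transcription factor gene (log2 0.94), Il5, whose product sustains eosinophils (log2 0.92), and the chemokine receptor gene Ccr4 (log2 0.65). Of 19 Th1 genes 2 rose, Ifng and the transcription factor gene Runx3 (11 when adjusted over the list alone, median 0.40). Of 34 cytokine and chemokine genes 5 rose and 1 fell, Ltb, which encodes lymphotoxin beta and is named because its value was seen (19 and 2 when adjusted over the list alone, median 0.31). With the preset correlation camera gave adjusted p values of 1.51e-10 for activation, 4.91e-05 for Th2, 1.7e-07 for Th1 and 9.84e-08 for cytokine genes. With an estimated correlation the adjusted p was 0.122 for activation and 0.281 for each of the others, and in fry the activation list passed (adjusted p = 0.0127). Each of the 10 gene calls named here other than that of Ltb, which was followed only without GATA1+SATB1 array 2 and vector array 9 and ended in both, ended without GATA1+SATB1 array 1 (adjusted p 0.0811 to 0.126), GATA1+SATB1 array 2 (0.0908 to 0.158) or vector array 9 (0.191 to 0.252), and 8, all but Nr4a2 and Egr2, with array weights (0.0594 to 0.0936). Calls also ended for Ccr4, Ifng and Runx3 without vector array 8 (0.0609, 0.0752 and 0.154), for Ccr8, Il5, Ccr4, Ifng and Runx3 without EOS+LEF1 array 1 (0.0514 to 0.0631), and for Runx3 after quantile normalization (0.054) or median centring (0.0503).

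A few genes of the proliferation and metabolism lists rose too. All 39 measured cell cycle genes lay above 0 with a median of 0.34. Of them 3 rose (28 when adjusted over the list alone): the mitotic kinase gene Plk1 (log2 0.57, adjusted p = 0.041), the spindle gene Nusap1 (log2 0.50, adjusted p = 0.0462) and the mitotic kinase gene Cdk1 (log2 0.46, adjusted p = 0.0489). In cholesterol synthesis 3 of 20 genes rose, the enzyme genes Nsdhl, Cyp51 and Hsd17b7 (8 when adjusted over the list alone, median 0.23). In the glycolysis list 3 of 19 rose (6 higher and 1 lower when adjusted over the list alone, median 0.19). These were the hypoxia-induced genes Egln3 and Bnip3, which encode no glycolytic enzyme (log2 1.04 and 0.64), and the glycolytic enzyme gene Pgam1 (log2 0.60). Camera with the preset correlation gave adjusted p values of 1.36e-17 for cell cycle, 1.67e-08 for cholesterol and 7.03e-05 for glycolysis genes. The adjusted p was 0.281, 0.281 and 0.342 with an estimated correlation. The cell cycle, cholesterol and glycolysis medians were 0.21, 0.14 and 0.08 without vector array 9, and the latter 2 were 0.37 and 0.31 without vector array 8. Each of the 9 gene calls ended without GATA1+SATB1 array 1 (adjusted p 0.0792 to 0.136), GATA1+SATB1 array 2 (0.0877 to 0.158) or vector array 9 (0.19 to 0.301, with log2 0.30 for Cdk1 and 0.29 for Cyp51), and 8, all but Bnip3, with array weights (0.0596 to 0.0856). Calls also ended for Plk1, Nusap1, Cdk1, Nsdhl and Cyp51 without EOS+LEF1 array 1 (0.057 to 0.0685), for Hsd17b7 and Cyp51 without GATA1+SATB1 array 3 (0.0538 and 0.058), for Plk1, Hsd17b7, Nsdhl, Pgam1 and Egln3 without vector array 8 (0.0503 to 0.0698), for Nusap1, Cdk1, Hsd17b7 and Cyp51 with median centring (0.0509 to 0.0606), and for Cdk1 after quantile normalization (0.057).

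Of 26 measured interferon-stimulated genes 2 fell, none rose and 5 lay above 0 (3 lower when adjusted over the list alone, median −0.11). Ifit3, whose product is part of the antiviral response, read 254 ± 9.78 (SD, n = 3) against 435 ± 94.3 (SD, n = 2; log2 −0.76, adjusted p = 0.0195), and its relative Ifit1 fell by 0.60 (adjusted p = 0.031). Camera passed with the preset correlation (adjusted p = 0.00881) and not with an estimated correlation (adjusted p = 0.559). The list lost its call without vector array 8 (median −0.08, adjusted p = 0.516). The calls of both genes ended without GATA1+SATB1 array 1 (adjusted p 0.0733 and 0.0975) or GATA1+SATB1 array 2 (0.0877 and 0.07), and that of Ifit1 also without vector array 8 (0.0998), without vector array 9 (0.139) and with array weights (0.0571).

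Of the markers of B cells 6 of 14, and of the genes of MHC class II antigen presentation 6 of 8, rose in the arrays labelled GATA1+SATB1, although the sort had excluded CD19+ cells. All 14 measured B cell markers lay above 0 (median 0.53; 10 higher when adjusted over the list alone). Ms4a1, which encodes CD20, rose 2.52-fold (adjusted p = 0.0283), Fcer2a, which encodes CD23, 2.14-fold (adjusted p = 0.0196), and Cd79a of the B cell receptor 2.02-fold (adjusted p = 0.0175). The adaptor gene Blnk rose by 0.59 on the log2 scale (adjusted p = 0.0196). All 8 measured MHC class II genes lay above 0 (median 0.73; 7 higher when adjusted over the list alone). Cd74, the invariant chain, reached 1776 ± 220 (SD, n = 3) from 769 ± 143 (SD, n = 2), 2.32-fold (adjusted p = 0.0154). H2-Aa, a class II chain, rose 2.67-fold (adjusted p = 0.0252), and Ciita, the master regulator of these genes, 1.48-fold (adjusted p = 0.0165). Cd180, a toll-like receptor family gene of B cells and myeloid cells, and Ly86, whose product binds CD180, rose 2.62-fold and 2.76-fold. Camera passed for B cell markers (adjusted p = 3.66e-11) and MHC class II genes (adjusted p = 1.56e-10) with the preset correlation. The adjusted p was 0.256 for both with an estimated correlation, and fry passed for MHC class II genes (adjusted p = 0.0349) and not for B cell markers (adjusted p = 0.0536). No left-out array ended the camera call of either list or moved its median by over 1.5 times. Each of the 9 gene calls ended without GATA1+SATB1 array 2 (adjusted p 0.0787 to 0.109) or vector array 9 (0.127 to 0.213), all but that of Cd180 without GATA1+SATB1 array 1 (0.0604 to 0.0914), that of Blnk without vector array 8 (0.0617), and that of Ly86 with array weights (0.0555) or a variance trend (0.0565).

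**Figure D2:**
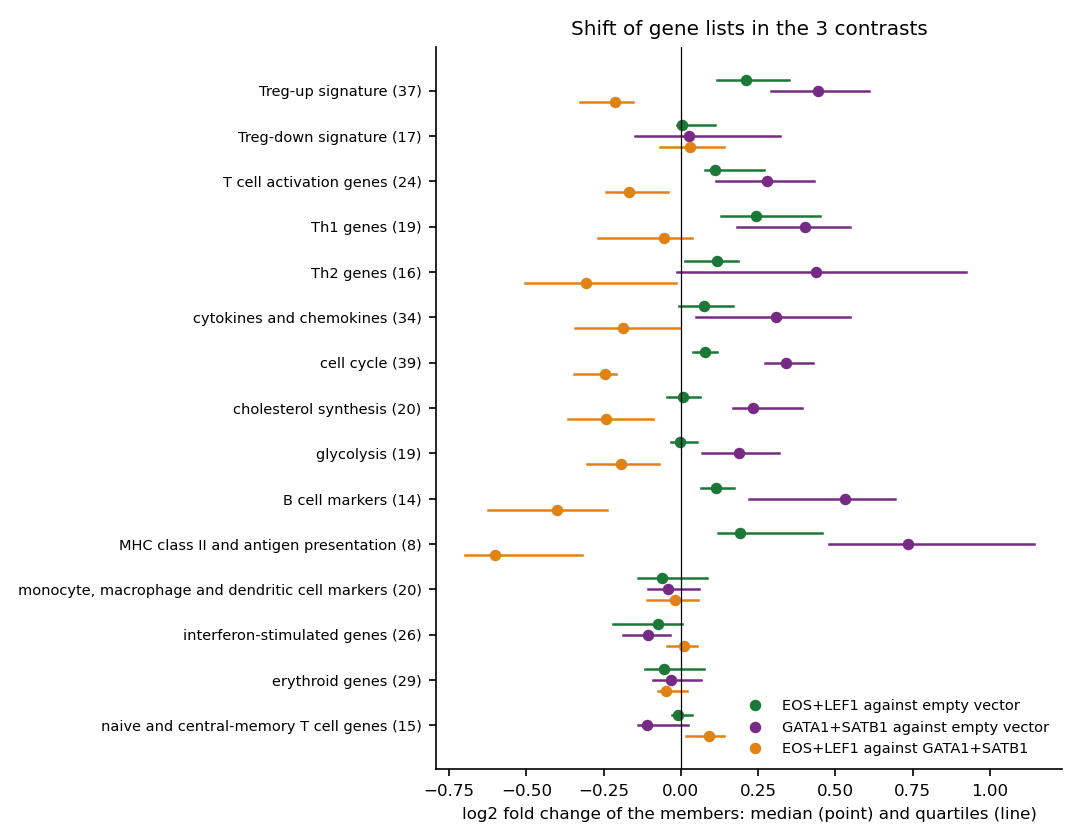
Median log2 difference of the members of 15 gene lists (points) with their quartiles (lines) in the 3 contrasts, with the number of measured genes in parentheses. In the arrays labelled GATA1+SATB1 the medians against empty vector were 0.44 for Treg-up genes, 0.53 for B cell markers and 0.73 for MHC class II genes, and −0.04 for monocyte, macrophage and dendritic cell markers.

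Markers of 4 other groups of cell types did not pass the list test in the arrays labelled GATA1+SATB1. Monocyte, macrophage and dendritic cell markers had a median of −0.04, with 8 of 20 above 0. Of these genes 2 rose (2 when adjusted over the list alone), the lysozyme gene Lyz2 (1.77-fold, adjusted p = 0.0195) and the lysosomal gene Cd68 (1.44-fold, adjusted p = 0.0196). Neutrophil markers leaned downward, with 2 of 13 above 0 (median −0.07), and 1 rose, Ly6g (log2 0.41). CD8 and NK cell markers leaned upward, with 13 of 15 above 0 (median 0.06) and 0 changed. Stromal and endothelial markers had 4 of 14 above 0 (median −0.06), and 1 fell, Pdpn (log2 −0.31). Adjusted over the list alone, 1, 0 and 2 of these genes passed. The camera adjusted p was 0.834, 0.644, 0.194 and 0.557 for the 4 lists. The calls of Lyz2, Cd68, Ly6g and Pdpn ended without GATA1+SATB1 array 1 (adjusted p 0.0777 to 0.119), GATA1+SATB1 array 2 (0.07 to 0.161) or vector array 9 (0.189 to 0.249). Those of Ly6g and Pdpn also ended without EOS+LEF1 array 1 (0.0649 and 0.0633) or vector array 8 (0.162 and 0.074), with median centring (0.05 and 0.0514), array weights (0.0875 and 0.0764) or only the 2 groups in the fit (0.0501 and 0.062), and that of Pdpn without GATA1+SATB1 array 3 (0.0704).

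Among lists of the lineages that GATA1 serves, only haem synthesis passed in the arrays labelled GATA1+SATB1. It also passed in the arrays labelled EOS+LEF1, which name no GATA1 (camera adjusted p = 0.0357, and 0.326 with an estimated correlation). There its camera call ended after quantile normalization (adjusted p = 0.243), among genes above the median level (0.232) and without EOS+LEF1 array 1 (0.092) or EOS+LEF1 array 3 (0.0767). Its median there was 0.08, and it was 0.02 without vector array 9 and 0.145 without vector array 8. In the arrays labelled GATA1+SATB1, erythroid genes had a median of −0.03 with 1 of 29 higher (1 when adjusted over the list alone), Mt2, which is not specific to red cells. Megakaryocyte genes had a median of 0.02 and mast cell, basophil and eosinophil genes of −0.06, with 0 of 17 and 0 of 23 changed (camera adjusted p = 0.944, 0.395 and 0.276 for the 3 lists). Of 8 haem synthesis genes 2 rose (3 when adjusted over the list alone), Alad and Alas1, whose product starts the pathway (log2 0.52 and 0.43, adjusted p = 0.0477 and 0.0481). Camera gave an adjusted p of 0.0154 (adjusted p = 0.281 with an estimated correlation). In the T cell receptor list 2 of 19 genes rose (2 when adjusted over the list alone). Thy1, a surface glycoprotein of mouse T cells, rose 1.56-fold, to 10557 ± 336 (SD, n = 3) from 6760 ± 76.3 (SD, n = 2; adjusted p = 0.00609), and the adaptor gene Trat1 by 0.42 (adjusted p = 0.0471). The list did not pass camera (adjusted p = 0.0634) and passed in fry (adjusted p = 0.0468). The call of Thy1 ended without vector array 9 (adjusted p = 0.0695), where those of Alad, Alas1 and Trat1 ended too (0.252 to 0.27), as they did without EOS+LEF1 array 1 (0.0622 to 0.0663), GATA1+SATB1 array 1 (0.0897 to 0.132), GATA1+SATB1 array 2 (0.156 to 0.163) and vector array 8 (0.0711 to 0.0946), with array weights (0.0809 to 0.0911) and with median centring (0.0559 to 0.0564), for Alas1 and Trat1 without GATA1+SATB1 array 3 (0.0515 and 0.0507), for Alad and Alas1 after quantile normalization (both 0.0549), and for Trat1 with only the 2 groups in the fit (0.0509). In the arrays labelled GATA1+SATB1 the haem list lost its call without vector array 9 (median 0.11) and among genes above the median level (camera adjusted p = 0.118). Its median there was 0.20 without vector array 8, against 0.13 with all arrays.

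Of the remaining T cell and stress lists, 5 passed camera with the preset correlation, each with few genes called. They were IL-2 and STAT5 response (1 of 20 higher, Tnfrsf9), chemokine receptors and integrins (3 of 30 higher, Ccr8, Ccr4 and Cxcr5), Th17 (1 of 11 higher, Il21), Tfh (2 of 14 higher, Il21 and Cxcr5) and heat shock genes (0 of 20 changed). Adjusted over the list alone, 9, 7, 4, 6 and 1 were higher and 0, 3, 1, 2 and 0 lower. Their camera adjusted p values were 0.00495, 0.0154, 0.0389, 0.0427 and 0.0242, and the adjusted p values were 0.342, 0.346, 0.346, 0.281 and 0.281 with an estimated correlation. Naive T cell genes (0 of 15 changed), Wnt targets (1 of 23 higher, the adhesion receptor gene Cd44) and apoptosis genes (1 of 18 higher, the killer gene Bak1, and 1 lower, the survival gene Mcl1) did not pass (adjusted p = 0.152, 0.194 and 0.875). Median and mean differed in sign for erythroid genes, Wnt targets, apoptosis genes and myeloid markers. The 5 camera calls ended without vector array 9 (adjusted p 0.0634 to 0.147) and among genes above the median level (0.0935 to 0.665), those of IL-2 response and heat shock genes without GATA1+SATB1 array 3 (0.0581 and 0.175), that of Th17 without GATA1+SATB1 array 1 (0.0702), those of Th17 and Tfh without vector array 8 (0.0624 and 0.0655), and that of Tfh without GATA1+SATB1 array 2 (0.0814) or EOS+LEF1 array 3 (0.0519). The calls of Tfh and heat shock genes ended after quantile normalization (0.091 and 0.0824), and that of Tfh with median centring (0.0544). The chemokine receptor median of 0.04 was 0.09 without GATA1+SATB1 array 1, 0.06 without vector array 8 and 0.02 without vector array 9. The calls of Cxcr5, Cd44, Bak1 and Mcl1 ended without GATA1+SATB1 array 1 (adjusted p 0.0914 to 0.125), GATA1+SATB1 array 2 (0.11 to 0.156), vector array 8 (0.0644 to 0.0945) or vector array 9 (0.204 to 0.252) and with array weights (0.0594 to 0.0863), those of Cxcr5 and Cd44 with median centring (0.052 and 0.0547), and that of Cd44 without EOS+LEF1 array 1 (0.058) or EOS+LEF1 array 3 (0.05).

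The comparison of the arrays labelled EOS+LEF1 with empty vector asks the same of the other pair. No gene passed the threshold in limma, but the Treg-up genes leaned upward. Of 37 such genes 36 lay above 0, with a median log2 difference of 0.21, and 0 passed over all genes or when adjusted over the list alone. Foxp3 read 1646 ± 313 (SD, n = 3) against 1189 ± 139 (SD, n = 2), a log2 difference of 0.46 (adjusted p = 0.367). The calcium-binding gene S100a6 differed by 0.61 (adjusted p = 0.367) and Entpd1, which encodes the ectoenzyme CD39, by 0.44 (adjusted p = 0.373). Of 17 Treg-down genes 10 lay above 0 and 2 were higher when adjusted over the list alone, with Ifng at 0.62 (adjusted p = 0.32 over all genes). Lyz2 came nearest to the threshold, at 304 ± 61.1 against 144 ± 4.36 (2.08-fold, adjusted p = 0.0554), followed by Thy1, at 9636 ± 339 against 6760 ± 76.3 (1.43-fold, adjusted p = 0.0922). Under an unadjusted p of 0.05 lay 2197 genes, 657 higher and 1540 lower, against 988 expected by chance. This unadjusted limma count was 1337 after quantile normalization and 1934 with median centring. Over the left-out factor arrays it ran from 1378 (EOS+LEF1 array 1) to 2230 (GATA1+SATB1 array 1). Camera passed for Treg-up genes with the preset correlation (adjusted p = 8.4e-13) and not with an estimated correlation (adjusted p = 0.326). The Treg-down list passed upward with a median of 0.00 (adjusted p = 0.0302, and adjusted p = 0.326 with an estimated correlation). The count of 0 was 1 without EOS+LEF1 array 1 or 3 and with either other scaling (Lyz2), 2 with a variance trend, a pseudocount of 16 or genes above the median level (Lyz2 and Thy1), and 5 without vector array 9 (Ear6, Epx, Ifit3, Olfr1249 and Scgb2b2, of which Ear6, Olfr1249 and Scgb2b2 are named because their values were seen). The Treg-up median was 0.13 without EOS+LEF1 array 1, 0.34 without EOS+LEF1 array 2, 0.33 without vector array 8 and 0.12 without vector array 9, and the Treg-down list lost its call without vector array 8 (adjusted p = 0.159), after quantile normalization (0.209) and among genes above the median level (0.795), with medians of 0.01, 0.03 and 0.05 without EOS+LEF1 array 1, EOS+LEF1 array 3 and vector array 9.

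Effector and interferon genes gave other list shifts of this comparison, with 0 members past the test over all genes. Of 19 Th1 genes 18 lay above 0 (median 0.24, 3 higher when adjusted over the list alone), with the chemokine gene Ccl5 at 0.79 (adjusted p = 0.318). Of 24 activation genes 22 lay above 0 (median 0.11, 2 higher when adjusted over the list alone). Of 26 interferon-stimulated genes 7 lay above 0 (median −0.07, 5 lower when adjusted over the list alone), with Ifit3 at −0.71 (adjusted p = 0.177) and Ifit1 at −0.65 (adjusted p = 0.193). B cell markers (12 of 14 above 0, median 0.11) and MHC class II genes (7 of 8 above 0, median 0.19) leaned upward here as well, with 0 members passing when adjusted over the list alone. With the preset correlation camera gave adjusted p values of 3.55e-08, 8.16e-07, 0.00661, 0.00743 and 0.00029 for these 5 lists. The adjusted p was 0.326, 0.307, 0.517, 0.509 and 0.326 with an estimated correlation. In all, 16 of the 29 lists passed with the preset correlation, 14 upward and 2 downward. With an estimated correlation 0 passed (lowest adjusted p 0.307), as in fry (lowest adjusted p 0.24). Median and mean differed in sign for naive T cell genes, megakaryocyte genes, glycolysis genes and myeloid markers. The Th1 median was 0.38 without EOS+LEF1 array 2, 0.11 without EOS+LEF1 array 3, 0.38 without vector array 8 and 0.15 without vector array 9, and the activation median was 0.17 without EOS+LEF1 array 2. The interferon list lost its call without EOS+LEF1 array 2 (camera adjusted p = 0.0956) or vector array 8. Its median was −0.05 without EOS+LEF1 array 2, −0.04 without vector array 8 and −0.11 without vector array 9. The B cell list lost its call without EOS+LEF1 array 1 (0.142) or vector array 9 and among genes above the median level (0.073). Its median was 0.05 without EOS+LEF1 array 1, 0.07 without vector array 9 and 0.19 without vector array 8.

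**Figure D3:**
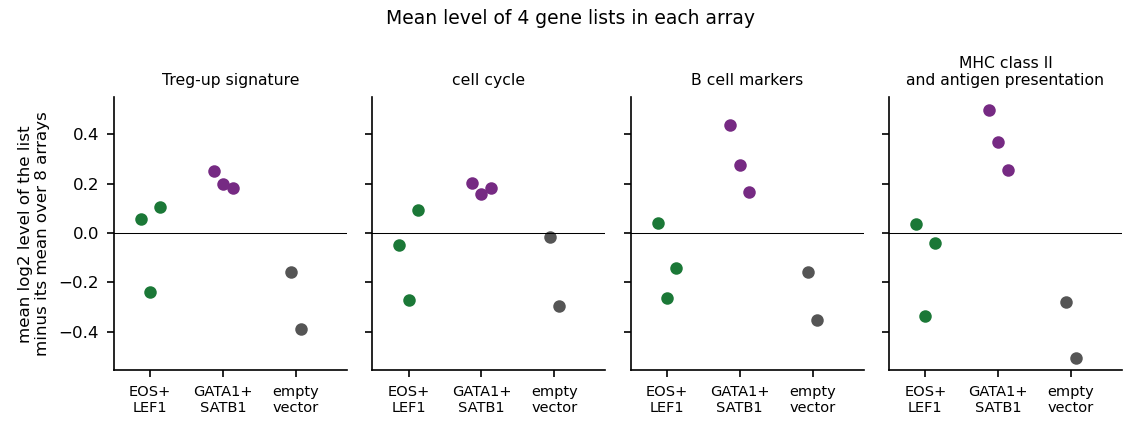
Mean log2 level of the genes of 4 lists in each of the 8 arrays, minus the mean of that list over all arrays. The 3 arrays labelled GATA1+SATB1 lay highest in each list (0.18 to 0.25 for Treg-up genes), and within their groups EOS+LEF1 array 2 (−0.24) and vector array 9 (−0.39) lay lowest.

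The last comparison sets the arrays of both pairs against each other. In the arrays labelled EOS+LEF1 142 genes were higher and 94 lower than in those labelled GATA1+SATB1, and 2 of the 236 differed at least 2-fold. Malat1 was 1.90-fold higher, at 5320 ± 645 against 2821 ± 505 (SD, n = 3 each; adjusted p = 0.0391). The ribosomal protein genes Rps21 and Rpl5 (log2 0.62 and 0.56) and the DNA-binding protein gene Purb (log2 0.70) were higher too. Among the lower genes were Cd180 (log2 −0.98, adjusted p = 0.0421), Scd1 (log2 −0.95, adjusted p = 0.0421) and Mef2c, a transcription factor gene active in B cells (log2 −0.84, adjusted p = 0.0391). The kappa segments Igkv10-96 and Igkv9-120 were lower (log2 −0.90 and −0.89), as were the lipid genes Fads2 and Tmem97 (log2 −0.75 and −0.74). In limma 3841 genes lay under an unadjusted p of 0.05, and the smallest adjusted p was 0.0391. Quantile normalization gave 146 higher and 160 lower, and median centring 310 and 82. The count was 0 without EOS+LEF1 array 1 or 2, without GATA1+SATB1 array 1 or 2, and without either vector array (unadjusted 2527 to 3957), so each gene named here lost its call in those 6 fits (adjusted p 0.0556 to 0.204). It was 0 with only these 6 arrays in the fit (unadjusted 3957), which for this contrast is the same fit as without either vector array. The 236 calls thus rest on a spread that includes the spread between the 2 vector arrays. The count was 809 without EOS+LEF1 array 3, 619 without GATA1+SATB1 array 3, 493 with a pseudocount of 16, 536 with a variance trend and 772 among genes above the median level. Calls also ended for Rps21 and Purb with the mean of a gene's probe sets (0.052 and 0.0516), for Rps21 and Rpl5 with array weights (0.0519 and 0.0525), and for Rpl5 after quantile normalization (0.051).

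Most Treg-up genes lay lower in the arrays labelled EOS+LEF1 than in those labelled GATA1+SATB1, 1 of them past the test. Treg-up genes had a median of −0.21 (5 of 37 above 0), and 1 fell, Lrrc32 (log2 −0.45, adjusted p = 0.0468; 8 lower when adjusted over the list alone). Foxp3 differed by −0.42 (adjusted p = 0.0917). Of 17 Treg-down genes 11 lay above 0 and 1 fell, Il21 (log2 −0.59, adjusted p = 0.0398; 4 higher and 1 lower when adjusted over the list alone). Of 16 Th2 genes 4 lay above 0 (median −0.31, 7 lower when adjusted over the list alone) and of 24 activation genes 4 (median −0.17, 1 higher and 7 lower when adjusted over the list alone), with 0 called in both over all genes. Of 34 cytokine genes 1 rose, Ltb (log2 0.48), and 1 fell, Il21 (median −0.19, 2 higher and 10 lower when adjusted over the list alone). Of 15 naive T cell genes 12 lay above 0 (median 0.09) and 0 were called. With the preset correlation camera gave adjusted p values of 5.04e-07 for Treg-up, 0.338 for Treg-down, 0.00535 for Th2, 0.00266 for activation, 0.00619 for cytokine and 0.012 for naive genes. With an estimated correlation the adjusted p was 0.67 for Treg-up, 0.67 for Th2, 0.608 for activation, 0.706 for cytokine and 0.678 for naive genes. The Treg-down median of 0.03 turned to −0.01 after quantile normalization and ran from 0.0056 to 0.0301 over the left-out arrays. Without EOS+LEF1 array 2 the medians were −0.14 for Treg-up, −0.11 for activation and −0.18 for Th2 (−0.47 without EOS+LEF1 array 3), and the calls of cytokine and naive genes ended without EOS+LEF1 array 2 (adjusted p = 0.15 and 0.053) or GATA1+SATB1 array 1 (0.0898 and 0.159), that of naive genes also after quantile normalization (0.255) and among genes above the median level (0.17). The calls of Lrrc32, Il21 and Ltb ended without EOS+LEF1 array 1 or 2, GATA1+SATB1 array 1 or 2, either vector array, or with only these 6 arrays (adjusted p 0.0556 to 0.199), and that of Lrrc32 without GATA1+SATB1 array 3 (0.0639).

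Most genes of the proliferation, metabolic and B cell lists lay lower in the arrays labelled EOS+LEF1 as well, few of them past the test. None of 39 cell cycle genes lay above 0 (median −0.25, 0 called over all genes and 17 lower when adjusted over the list alone). In cholesterol synthesis 2 of 20 genes fell, Hsd17b7 and Nsdhl (9 when adjusted over the list alone, median −0.24), and in the glycolysis list 3 of 19, Egln3, Bnip3 and Pgam1 (1 higher and 6 lower when adjusted over the list alone, median −0.20). Of 14 B cell markers 5 fell, Cd79a, Ebf1, Blnk, Fcer2a and Cd22, the last named because its value was seen (9 when adjusted over the list alone, median −0.40), with Cd79a at −0.88 (adjusted p = 0.0391). Of 8 MHC class II genes 4 fell, Cd74, H2-Eb1, H2-DMa and Ciita (6 when adjusted over the list alone, median −0.60), with Cd74 at −0.77 (adjusted p = 0.0444). With the preset correlation camera gave adjusted p values of 1.07e-10 for cell cycle, 2.84e-06 for cholesterol, 0.000287 for glycolysis, 1.68e-07 for B cell and 4.08e-06 for MHC class II genes. With an estimated correlation the adjusted p was 0.67 for the first 3 of these lists and 0.608 for the other 2. In fry 0 of the 29 lists passed (lowest adjusted p 0.128). Median and mean, or either and the test, differed in sign for chemokine receptors, interferon-stimulated genes, mast cell genes, CD8 and NK cell markers and neutrophil markers. Without EOS+LEF1 array 2 the medians were −0.16 for cell cycle and −0.11 for glycolysis genes. The gene calls named here, except that of Cd22, which was not followed, ended without EOS+LEF1 array 1 or 2, GATA1+SATB1 array 1 or 2, either vector array, or with only these 6 arrays (adjusted p 0.0556 to 0.199), and that of Egln3 also with the mean of a gene's probe sets (0.0501), a variance trend (0.0568) or array weights (0.0515).

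Both contrasts against empty vector use the same 2 vector arrays, which by itself makes their differences go the same way. Of the 439 genes called in the arrays labelled GATA1+SATB1, 408 (92.9%) had the same sign in the arrays labelled EOS+LEF1. Their median difference in the direction of the call was 0.16 in the latter, against 0.50 in the former. All 8 arrays were also simulated 100 times with no gene changed and 2 vector arrays shared by both contrasts. There the 439 genes with the smallest p for GATA1+SATB1 had the same sign for EOS+LEF1 in 95.65% on average (highest 97.27%). Genes changed by a single pair were not simulated, so the share of 92.9% cannot show whether the pairs act alike. Over all genes the share with the same sign was 71.09%, against a simulated 70.46% (highest 71.14%). No gene was called in both by limma, and 807 genes lay under an unadjusted p of 0.05 in both with the same direction. Of these 341 were higher and 466 lower, where independent lists would share 72 and 133. The log2 differences correlated across genes at r = 0.5605, genes not being independent replicates. The same simulations gave r = 0.5996 and 271.5 shared genes. The covariance was 0.0123 against a simulated 0.00512. The 2 vector arrays are too few to split, so it cannot be told how much of the gap in shared genes and covariance comes from them. The simulations changed no gene and drew each gene independently. By chance 988 genes per contrast would lie under an unadjusted p of 0.05 in limma, against 2197 and 3877 observed. The 807 shared genes against 271.5 therefore cannot show whether the pairs act alike either. The correlation was 0.3946 without EOS+LEF1 array 3 and 0.7219 without vector array 8. Of the genes called in the arrays labelled GATA1+SATB1 against empty vector, 121 were also among the 236 called between the pairs. Of these 73 were higher and 48 lower in the arrays labelled GATA1+SATB1. These contrasts share the 3 arrays labelled GATA1+SATB1, and the overlap that this alone gives was not simulated.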

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

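All tests in this part were chosen only after the result was seen. In a limma fit to all 24922 probe sets, 38 of the 3497 probe sets without a single gene name, which no comparison above used, passed the threshold between the arrays labelled GATA1+SATB1 and empty vector, 30 higher and 8 lower, among 251 calls in all.

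B cell markers and MHC class II genes leaned upward in the arrays labelled GATA1+SATB1, 6 of 14 and 6 of 8 past the test. Their 14 and 8 measured genes stand in no other list, but across arrays these lists moved with the Treg-up and cell cycle lists. In each of them EOS+LEF1 array 2 and vector array 9 lay lowest in their groups. Both arrays also lay close together on the main axis of variation over all genes (39.9% of the variance), at −13.68 and −13.98. The arrays labelled GATA1+SATB1 lay at 7.07 to 15.44 on it. RNA from monocytes, macrophages or dendritic cells cannot be told apart as a source of the MHC class II genes: their 20 markers had a median of −0.0402 (quartiles −0.107 and 0.0576), below the lower quartile of 0.479 of the MHC class II genes, but most lie at low levels (median 130, against 204 for all genes), and 2 of them, Lyz2 and Cd68, rose, although the sort against CD11b and CD11c would remove most of these cells. RNA from B cells is a candidate source that stays open: 13 other B cell genes, in no list, had a median of 0.279 (quartiles 0.183 and 0.495) with 11 above 0 and 4 higher, although the sort against CD19 would remove B cells. Levels in these arrays and in empty vector were 1776 and 769 for Cd74, 932 and 352 for H2-Aa, 694 and 451 for Cd79b, 236 and 60.6 for Igkv10-96, and 219 and 188 for Ighm (Cd79b and Ighm were chosen after their values were seen), and 5 probe sets shared by immunoglobulin genes only were among the 30 that were higher (log2 0.65 to 1.02). A change of these genes within the transduced T cells stays open and was not tested.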

How the results depend on the processing

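For EOS+LEF1 against empty vector the count of 0 became 1 after quantile normalization or median centring and 2 among genes above the median level, with the intensity trend or with a pseudocount of 16, and 0 to 5 over the left-out arrays. For GATA1+SATB1 against empty vector 439 became 882 among genes above the median level, 64 with array weights, 8 at an adjusted p under 0.01, 19 at 2-fold or more, 251 in the fit of all probe sets (chosen after the data were seen), and 4 to 656 over the left-out arrays. For EOS+LEF1 against GATA1+SATB1 236 became 392 with median centring, 772 among genes above the median level, 536 with the trend, 493 with the pseudocount, 2 at 2-fold or more, 0 at an adjusted p under 0.01 (limma, 3841 unadjusted), 0 with only the 2 groups in the fit (3957 unadjusted), 0 in the fit of all probe sets (4733 unadjusted), and 0 to 809 over the left-out arrays. The cause of these moves was not tested. With the replicate number as a block this contrast gave 0 calls (3737 unadjusted) and its 9 called lists beside the Treg lists kept theirs. Same-numbered arrays correlated at 0.192, 0.0664 and −0.111 in their deviations, against at most −0.0271, 0.13 and 0.101 with another number. Only number 1 correlated best with its own number. Such weak values from 3 arrays per group cannot decide whether the numbers pair the samples, and the labels do not say.

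The Treg-up medians of 0.2092 and 0.4443 against empty vector and −0.2146 between the pairs lost their call with an estimated correlation (adjusted p = 0.326, 0.256 and 0.67) and in fry (0.313, 0.0536 and 0.262), and kept it in each other setting run. The Treg-down median for EOS+LEF1 against empty vector, 0.004301 with either of those tests (0.326 and 0.313), was 0.008893 after quantile normalization (0.209) and 0.003756 among genes above the median level (0.795), each without a call, and 0.0003621 to 0.05462 over the left-out arrays. After quantile normalization it turned to −0.005648 for GATA1+SATB1 against empty vector and to −0.005718 between the pairs, and over the left-out arrays it ran from −0.02433 to 0.09566 in the former. For EOS+LEF1 against empty vector the T cell receptor list turned to −0.02457 after quantile normalization, and the cell cycle list ran from −0.06704 to 0.2162 over the left-out arrays. The correlation of the contrasts against empty vector ran from 0.3946 to 0.7219. The cause was not tested for any of these. Of 39 other list calls, 29 kept theirs under quantile normalization, 35 under median centring, 24 among genes above the median level, 26 without vector array 9 and 0 with an estimated correlation. Of 115 gene results followed, 110 kept direction and side of the threshold under quantile normalization, 102 under median centring, 67 with array weights, 13 without GATA1+SATB1 array 1, 9 without array 2 and 9 without vector array 9, and none turned in any setting. Background signal was not given, so what signal over background limits cannot be stated.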

Other observations

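All tests in this part were chosen only after the result was seen, except the count of other splits. Gene classes formed by symbol after the data were seen also differed in their medians. Of 50 small nucleolar RNA genes, most of which guide modification of ribosomal RNA, 2 were higher and 8 lower in the arrays labelled GATA1+SATB1 than with empty vector (median −0.23). In the arrays labelled EOS+LEF1 10 were higher than in those labelled GATA1+SATB1 (median 0.28). Ribosomal protein genes had medians of −0.15 (0 of 53 called in limma) and 0.25 (4 higher) in the same contrasts. In limma's camera with an estimated correlation, adjusted over 5 classes and 3 contrasts, the adjusted p was 0.266 and 0.218 for the first class and for the second. Of 10 immunoglobulin genes 3 were higher in the arrays labelled GATA1+SATB1 than with empty vector (median 0.37), and 4 were lower in the arrays labelled EOS+LEF1 than in those labelled GATA1+SATB1 (median −0.31). Their adjusted p with an estimated correlation was 0.0295 in both contrasts. Of 31 histone genes 3 were higher in the arrays labelled GATA1+SATB1 than with empty vector (median 0.23, adjusted p = 0.218 with an estimated correlation).

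In a contrast of all 6 factor arrays with empty vector, chosen after the data were seen, 11 genes differed, 9 higher and 2 lower. Igkv10-96 had the smallest p and Thy1 came next (log2 0.58, adjusted p = 0.00882), followed by Cd80, a costimulatory ligand (log2 0.74), and Lyz2 (log2 0.94), while Ifit3 was lower (log2 −0.73); Cd80 is named because its value was seen. The count was 19 after quantile normalization, 7 with median centring, 6 among genes above the median level, and over the left-out arrays 3 (either vector array), 4 (EOS+LEF1 array 1 or 3), 6 (GATA1+SATB1 array 2 or 3), 8 (GATA1+SATB1 array 1) and 126 (EOS+LEF1 array 2).

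Treg-up genes leaned upward in the arrays labelled GATA1+SATB1, 9 of 37 past the test. RNA from B cells would not raise the 14 members that B cells lack, whose median was 0.463 (quartiles 0.317 and 0.711). All 37 had already been seen to lie above 0, so the outcome for these 14 was known beforehand and is no independent test. For the other 23 members, with a median of 0.444 (0.298 and 0.569), RNA from B cells cannot be told apart, since B cells can express them. A larger share of Treg cells would lower the Treg-down genes that are not cytokines, but these 11 had a median of −0.0236 with quartiles on both sides of 0 (−0.295 and 0.036), so the test decides nothing, although the sort against CD25 would remove most Treg cells. A broad activation or effector change stays open and cannot be told apart: the 50 activation, Th1 and Th2 genes outside the Treg-up list had a median of 0.297 (0.0864 and 0.533), but those lists had already been seen to lie higher. An action of the transduced factors on Treg genes, the biological difference the design names, stays open and was not tested apart from these.

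None of the transduced genes passed the threshold in the arrays labelled with it, while Thy1 was higher in the 6 factor arrays than with empty vector. Exchanged labels of the factor groups cannot be told apart from correct ones, since the largest difference of a factor gene under the other label was 0.334 and did not pass the threshold. Probe sets that see little of the transduced cDNA could account for the largest difference under a gene's own label being only 0.288. This stays open because the table does not give the probes' place in the genes. The values themselves do not show that the transduced cDNAs were expressed. A Thy1 marker carried by a vector used only in the factor groups cannot be told apart from an effect of the factors on Thy1. The difference of Thy1, 0.577, against at most 0.236 for the other 18 genes of the T cell receptor list (quartiles −0.0296 and 0.0846), would come from either. The labels name pMIG, a vector with a GFP marker, for the empty-vector arrays and no vector or marker for the factor groups. They also do not say whether the vector and factor arrays were prepared together, so a difference in preparation cannot be told apart from these.

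For the 236 genes called between the arrays of both pairs, the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many calls came from 1 of the 10 splits, the real one, and the highest count among the others was 0 (limma, with 278 to 1606 genes under an unadjusted p of 0.05).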
